A study of Mus musculus with 6 samples.

How the data were processed

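Total RNA was isolated from sorted GFP-positive or GFP-high, CD11b-positive bone marrow cells with low Gr1 (3 samples) or high Gr1 (3 samples), and 100 ng per sample were labelled with biotin for 3' expression arrays, per the labels' protocols. The deposited values are log2 probe set values, which the authors made with GCRMA per the submitters' processing notes. GCRMA as usually run subtracts a background estimated from probe sequence, equalizes the distributions of the arrays and summarizes each probe set, but its version and settings are not given in the sources used here. The log2 scale was checked on the values, which ran from 0.87 to 15.01 with array medians between 2.86 and 2.94 and no centring of single probe sets. The deposited table had 45101 probe sets, no missing value and no detection calls. A low value thus cannot be told from an absent transcript except by its distance from the control probe sets of absent transcripts. These were 3 probe sets, and their highest value was 2.77. The description of Gr1lo replicate 3 writes the reporter in a form that can be read as GFP-negative or as a hyphen; its title and marker labels are those of the Gr1lo group, and it was kept there.

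Probe sets were named through a table of the platform annotation. After 64 control probe sets were set aside, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had no gene listed there; only probe sets with 1 symbol named genes. Entrez identifiers of 18032 genes were found in the RefSeq table of assembly GRCm38.p6, which was used for names only, and it updated 0 symbols. No coordinates are given. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays, a rule that does not look at the groups. A gene was kept where at least 3 of 6 arrays lay above that array's 40th percentile, which left 12739 genes and set 5454 aside. In 68 of the called genes another kept probe set was called the other way.

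Gr1hi was compared with Gr1lo by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The fit had 4 residual degrees of freedom and 5.11 prior degrees of freedom. The median SD between replicates was 0.151 in Gr1lo and 0.153 in Gr1hi. Lists of genes for cell types, granules, cell cycle, metabolism and signalling were fixed before the data were examined, as were the contrast, the filter and most of the alternatives. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 31 lists, and again with the correlation estimated and with fry. Sex-linked genes and the reporter and sorted antigens were read as checks. Counts adjusted over the list alone use the p-values of the same fit.

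The genes named were set beforehand as well. They were the 12 with the largest difference in each direction among called genes whose groups did not overlap and whose level in the higher group lay above that group's median, leaving out provisional symbols and antigen receptor segments, all members of the sorted antigen, histamine and sex-linked lists, and up to 4 members of each other list with the smallest p. Other genes, such as those that went against their list, and all gene families in the closing section, were chosen after their values were seen.

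The fit was tested on simulated data for this comparison, over 12739 genes with 50 changed at each of 4 sizes: at a log2 change of 0.5, 1, 2 and 4 it recovered 20%, 54%, 92% and 100%, with 3 false calls (2.21% of calls). Far fewer genes were changed in that simulation than were called in the data, so its shares recovered and called falsely need not hold there. The list test called 5 of 5 shifted lists and 0 of the others on simulated genes that vary independently, which real genes do not. Alternatives were no filter, a filter at the 60th percentile, the mean of a gene's probe sets, each probe set on its own, eBayes without the trend or with robust estimation, repeated quantile normalization, arrays centred on the median of kept genes, array weights, the replicate number as a block, a threshold of 0.01, a test against a 1.5-fold change, and each array left out in turn. Added after the data were seen were both replicate 3 arrays left out, a factor for the replicate 3 arrays, a filter at log2 5, and centring on the hybridization controls. A change of pseudocount did not apply, since the values were already log2. Simple summaries and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Replicate arrays differed in their values, and the arrays' number limits the precision.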

Results

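Gene expression was measured with Affymetrix 3' expression arrays in myeloid cells sorted from the bone marrow of femur and tibia of Hdc-GFP reporter mice on a C57BL/6 background. In these mice green fluorescent protein reports the activity of Hdc, the gene of histidine decarboxylase, which makes histamine from histidine. All sorted cells were positive or high for GFP and positive for CD11b, an integrin of myeloid cells. They were divided by the antigen Gr1, which the Gr1 antibody detects on Ly6G and Ly6C, into a Gr1lo group (3 arrays) and a Gr1hi group (3 arrays). The comparison asks which genes differ between the Gr1lo and the Gr1hi cells, and every difference is given as Gr1hi minus Gr1lo on the log2 scale. Values are log2 probe set values made with GCRMA, with 1 probe set per gene, and the number of arrays limits their precision. The labels do not say whether the replicates are separate animals, so p-values measure only the spread between these samples.

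Gr1hi cells held far less transcript of the primary granule proteases and of the cell division machinery, and far more transcript of genes of mature neutrophils, interferon-responsive genes and pathogen sensors. Elane, which encodes neutrophil elastase, fell from 11.61 ± 0.35 in Gr1lo to 4.62 ± 0.61 in Gr1hi (SD, n = 3 per group). Il1b, which encodes the cytokine interleukin-1 beta, rose from 5.24 ± 1.33 to 12.62 ± 0.27. Of 27 tested G2/M genes 27 fell, and of 22 tested mature neutrophil genes 20 rose. Hdc itself, whose reporter was used to sort both groups, rose from 10.86 ± 0.12 to 12.33 ± 0.30.

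The genes of the reporter and of the sorted antigens were set as a check of the labels. Both groups were sorted for GFP and CD11b, so Hdc and Itgam cannot tell which arrays are Gr1lo or Gr1hi. Hdc differed by 1.47 (SE 0.14, limma adjusted p = 1.84e-05), a 2.77-fold difference, and its other probe set differed by 2.08. Itgam, which encodes CD11b, rose by 0.89 (SE 0.11, adjusted p = 7.53e-05). The Gr1 antigen itself could not be checked, because no probe set used here names Ly6g, Ly6c1 or Ly6c2 alone.

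All 6 samples are labelled female. Eif2s3y, a gene of the Y chromosome, nevertheless lay between 9.02 and 10.66 on all 6 arrays, against a mean of 2.39 in Gr1lo and 2.50 in Gr1hi for the controls of absent transcripts. Xist, the transcript of the inactive X chromosome, read 2.34, 1.97 and 10.95 in Gr1lo replicates 1, 2 and 3, and 2.28, 2.43 and 10.14 in Gr1hi replicates 1, 2 and 3. Eif2s3y was higher in Gr1hi by 0.77 (limma adjusted p = 0.023), a call lost without Gr1lo replicate 3 (0.0605), Gr1hi replicate 1 (0.0857) or Gr1hi replicate 2 (0.0704; 0.000268 to 0.1 over all alternatives). Kdm5d, also Y-linked, stood at 4.63 ± 0.76 and 5.48 ± 0.31, and Uty at 3.26 ± 0.31 and 3.28 ± 0.11 (limma adjusted p = 0.0673 and 0.907). Kdm5d passed the test without Gr1lo replicate 2 (adjusted p = 0.0143; 0.00165 to 0.196 over all alternatives). The transcripts of all 6 arrays thus include those of a Y chromosome, which the label does not give. In replicates 1 and 2 of both groups Xist was no higher than 2.43, within the absent-transcript level. Together with Eif2s3y this argues against the female label for these arrays.

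**Figure D1:**
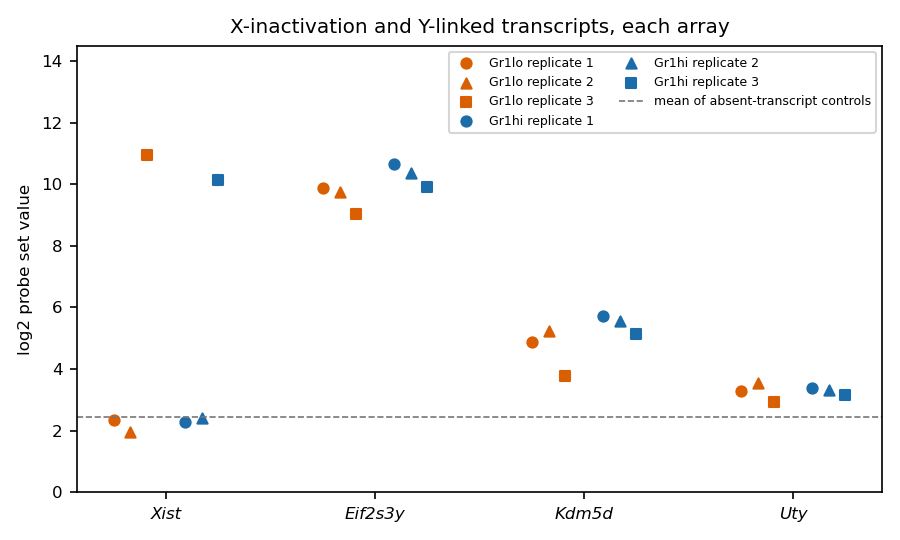
Log2 probe set values of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 6 arrays (orange, Gr1lo; blue, Gr1hi; circle, triangle and square, replicates 1, 2 and 3), with the mean of the absent-transcript controls as a dashed line. Xist lies at 10.95 and 10.14 in replicate 3 of the groups and no higher than 2.43 on the other arrays, while Eif2s3y lies at 9.02 or above on every array.

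Of 12739 tested genes, 7179 (56.4%) differed at an adjusted p under 0.05, 3128 higher and 4051 lower in Gr1hi. At least 2-fold differences were found in 3817 genes (1350 higher, 2467 lower) and at least 8-fold differences in 786 (242 higher, 544 lower). The arrays of the groups did not overlap in 8340 genes (65.5%), where chance gives 10%. Correlations between arrays were 0.992 to 0.996 within Gr1lo, 0.994 to 0.995 within Gr1hi and 0.916 to 0.942 between the groups. The balance of directions rests on the scaling: 43.6% of the called genes were higher in Gr1hi on the deposited scale, 78.3% (8354 higher, 2313 lower) with arrays centred on the median of the kept genes, and 27.7% (1861 higher, 4848 lower) with arrays centred on the hybridization controls. The median difference of all tested genes was 0.03 on the deposited scale, 0.70 after the first centring and -0.23 after the second so the direction of smaller differences rests on the scaling. The constant of the first centring would also put genes of tissues outside blood, with a median of 0.05 on the deposited scale, higher in Gr1hi. Which scale is closest to the amounts in the cells was not tested.

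Among genes above the median level in their higher group, the largest rises after Il1b (7.38, 166-fold) were in Steap4 (7.12), Acod1 (7.08), Sirpb1a (6.94), Hcar2 (6.93) and Slc15a3 (6.51). Steap4 encodes a metalloreductase and Acod1 the enzyme that makes itaconate. They were followed by Pla2g7 (6.50), the interferon-responsive antiviral gene Rsad2 (6.50), the aquaglyceroporin gene Aqp9 (6.45), Oasl2 (6.43), the lectin gene Clec4n (6.34) and Basp1 (6.25). Each of these 12 had an adjusted p of 5.56e-05 or lower. Their order rests on gaps smaller than the SD of Il1b between the Gr1lo replicates. In Gr1lo, Hcar2 at 2.24 ± 0.72, Oasl2 at 2.40 ± 0.22 and Clec4n at 2.40 ± 0.10 lay at the level of the absent-transcript controls, so the size of their difference depends on that background. Of the genes named below, Ifit1, Ms4a1, Cd6, Lat, Prf1, Eomes, Klre1, Pf4, Cdh5 and Col1a1 in Gr1lo, and Wdr12 and Hemgn in Gr1hi, also had a mean below 2.77, the highest value of those controls. The same limit holds for them.

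The largest falls after Elane (-6.99, 127-fold) were in Cst7 (-6.44), the thymidine kinase gene Tk1 (-6.36), the metallothionein gene Mt1 (-6.35), Hacd1 (-6.33) and Nkg7 (-6.31). The helicase subunit genes Mcm2 (-6.24) and Mcm3 (-6.17), Fignl1 (-6.15), Hells (-6.10), Dmkn (-6.03) and the glutathione transferase gene Gstm1 (-5.90) came next. All 12 had an adjusted p of 1.59e-06 or lower. Dmkn ended at 2.17 ± 0.45 in Gr1hi, within the absent-transcript level.

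Granule genes split by granule type. Of 8 tested primary (azurophil) granule genes 7 fell, and the same 7 did so adjusted over the list alone. Besides Elane and Cst7, the serine protease genes Prtn3 and Ctsg fell by 4.46 and 4.39, the latter from 13.29 ± 0.26 to 8.90 ± 0.44. Mpo, which encodes myeloperoxidase, fell by 3.98, while Srgn, which encodes the proteoglycan serglycin of granules in general, rose by 0.35 and lost that rise with arrays centred on the hybridization controls. The list's camera test gave an adjusted p = 6.91e-04, and an adjusted p = 0.371 with an estimated correlation.

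Of 18 tested secondary and tertiary granule genes 10 rose and 0 fell, and 10 rose adjusted over the list alone. Those that rose include the collagenase gene Mmp8 (11.41 ± 0.72 to 13.88 ± 0.03), Ceacam10 (by 2.33), the gelatinase gene Mmp9 (by 2.01) and Padi4 (by 1.38). The lactoferrin gene Ltf (14.16 ± 0.16 and 14.32 ± 0.07), Lcn2 (14.38 ± 0.06 and 14.49 ± 0.05), Camp (14.66 ± 0.13 and 14.70 ± 0.03) and Ngp (14.42 ± 0.15 and 14.54 ± 0.03) lay near the top of the arrays' range in both groups and did not pass the test. With arrays centred on the hybridization controls 4 of the 18 rose and 1 fell. The list's camera adjusted p was 0.00167, and its adjusted p = 0.427 with an estimated correlation.

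Of 22 tested mature neutrophil genes 20 rose and 0 fell, adjusted over the list alone as well. They include Cxcr2, a chemokine receptor of neutrophils, which rose from 7.89 ± 0.47 to 10.88 ± 0.11, and Csf3r, the receptor of granulocyte colony-stimulating factor, which rose from 9.57 ± 0.38 to 12.26 ± 0.20. Il1rn rose by 4.21, Stfa3 by 4.74 and Mxd1 by 1.90. S100a8 (14.87 ± 0.05 and 14.94 ± 0.03) and S100a9 (14.89 ± 0.06 and 14.99 ± 0.03) were at the top of the range in both groups. The list's mean difference was 2.88 with a camera adjusted p = 2.89e-10, and adjusted p = 0.294 with an estimated correlation.

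Cell cycle genes were lower throughout in Gr1hi. In the G2/M list 27 of 27 tested genes fell, and 27 did so adjusted over the list alone. Mki67, a marker of cycling cells, fell from 12.90 ± 0.11 to 10.29 ± 0.08, Top2a from 12.70 ± 0.01 to 9.92 ± 0.12, Birc5 by 3.41 and Bub1b by 4.19. In the DNA replication list 31 of 32 fell, and 32 adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell by 3.34, Mcm5 by 4.27 and Mcm7 by 3.88. Mki67 and Top2a stayed well above the background level in Gr1hi, whereas Tk1 ended at 3.27 ± 0.18. Camera adjusted p-values were 8.23e-16 and 5.41e-17, and adjusted p = 0.294 for each list with an estimated correlation. The falls held under every scaling tried, with 26 of 27 and 31 of 32 genes called after centring on the median of kept genes.

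**Figure D2:**
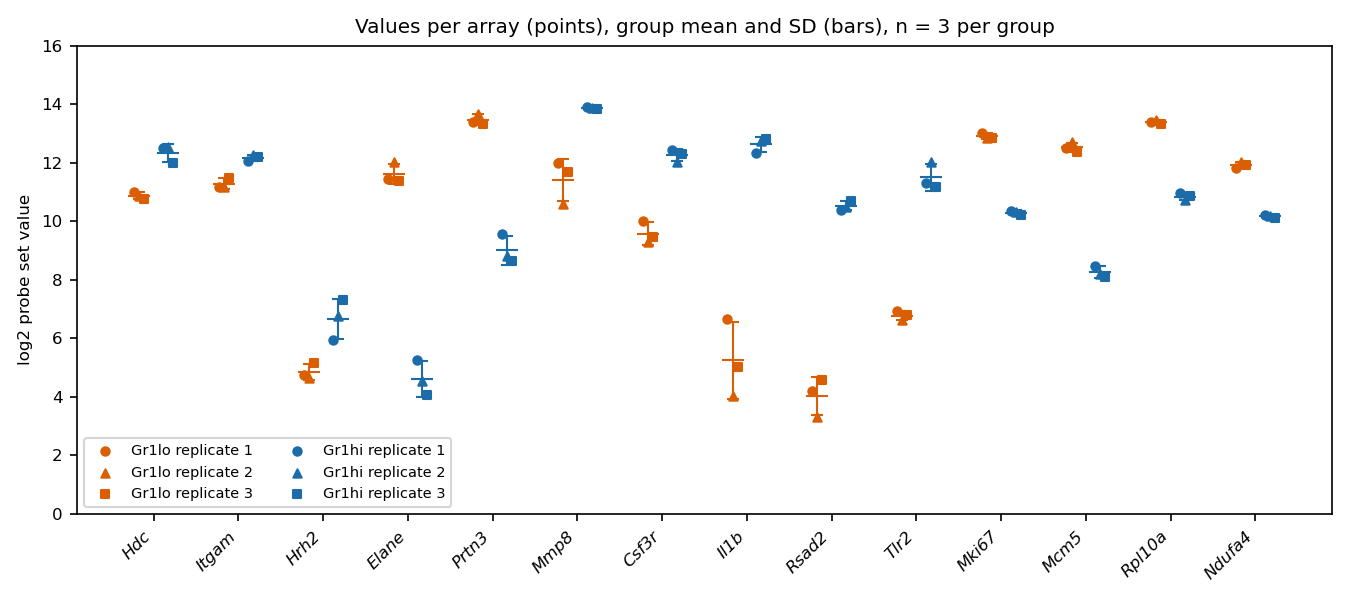
Log2 probe set values of 14 genes on each array (orange, Gr1lo; blue, Gr1hi; circle, triangle and square, replicates 1, 2 and 3), with horizontal marks for group means and vertical bars for the SD (n = 3 per group). The Gr1hi arrays lie above the Gr1lo arrays for Hdc, Mmp8, Csf3r, Il1b, Rsad2 and Tlr2, and below them for Elane, Prtn3, Mki67, Mcm5, Rpl10a and Ndufa4.

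Genes of ribosomes and of their assembly were lower in Gr1hi as well. Of 26 tested cytosolic ribosomal protein genes 24 fell and 0 rose (25 adjusted over the list alone), among them Rpl10a (13.38 ± 0.08 to 10.84 ± 0.12), Rps19 (by 2.03), Rps18 (by 2.19) and Rpsa (by 2.21). After centring on the median of kept genes 22 fell and 2 rose. Of 28 tested ribosome biogenesis genes 24 fell (25 adjusted over the list alone) and 1, Polr1a, rose by 2.27. The fibrillarin gene Fbl fell from 10.19 ± 0.66 to 6.02 ± 0.12, Nop58 by 4.53, Wdr12 by 4.33 and Npm1 by 2.68. Camera adjusted p-values were 3.69e-11 and 1.36e-06, and adjusted p = 0.323 and adjusted p = 0.414 with an estimated correlation.

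Of 30 tested oxidative phosphorylation genes 25 fell and 0 rose (26 adjusted over the list alone) on the deposited scale, whereas 12 fell and 6 rose after centring on the median of kept genes. Ndufa4 fell from 11.92 ± 0.11 to 10.17 ± 0.05, Ndufv1 by 1.53, Ndufb5 by 1.61 and Atp5o by 1.38. The camera adjusted p was 2.09e-07, and adjusted p = 0.322 with an estimated correlation. In the glycolysis list 10 of 19 rose and 3 fell, also adjusted over the list alone, while 4 rose and 4 fell with arrays centred on the hybridization controls. The glucose transporter genes Slc2a1 and Slc2a3 rose by 2.04 and 1.31 and the phosphofructokinase regulator gene Pfkfb4 by 1.37, whereas the lactate dehydrogenase gene Ldhb fell from 8.23 ± 0.39 to 3.77 ± 0.32 and Tpi1 fell by 1.27. The glycolysis list did not pass the list test (camera adjusted p = 0.0621), but did without Gr1hi replicate 1 (0.0395; 0.0113 to 0.362 over all alternatives).

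Interferon-responsive genes were higher in Gr1hi: 21 of 26 tested rose and 1 fell, with the same counts adjusted over the list alone. Oasl2 rose by 6.43, Ifi27l2a from 4.72 ± 0.17 to 9.92 ± 0.31, Rsad2 from 4.03 ± 0.65 to 10.53 ± 0.16 and Trim30a from 8.77 ± 0.13 to 11.41 ± 0.23. Irf7, a regulator of the response, rose by 2.24. Ifit2 was the exception and fell from 8.41 ± 0.27 to 6.12 ± 0.67, while its relatives Ifit1 and Ifit3 rose by 4.10 and 4.54. Mx1 (difference 0.28, adjusted p = 0.12) and Cxcl10 (0.31, adjusted p = 0.338) did not pass the test. For the list, the camera adjusted p was 1.71e-08, and adjusted p = 0.323 with an estimated correlation.

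Sensors of microbes rose in 18 of 22 tested genes and fell in 1, with the same counts adjusted over the list alone. Tlr2 rose from 6.77 ± 0.16 to 11.50 ± 0.46, Cd14 from 3.04 ± 0.37 to 8.28 ± 0.71, Ly96 by 4.90, Tlr13 by 5.02, Tlr5 by 1.92 and Nlrp3 by 3.34. In Gr1lo, Ly96 at 2.72 and Tlr5 at 2.00 lay within the absent-transcript level, so the size of their rise depends on background. Pycard, an adaptor of inflammasomes, fell by 0.65, but differed by 0.02 after centring on the median of kept genes, where 21 of the list rose and 0 fell. The camera adjusted p was 9.13e-07, and adjusted p = 0.294 with an estimated correlation. Of 16 tested phagocytosis and Fc receptor genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; 14 and 0 after centring on the median of kept genes), among them the Fc receptor genes Fcgr4 (by 2.61) and Fcgr3 (by 1.26) and the kinase gene Syk (by 1.33). The inhibitory Fc receptor gene Fcgr2b fell from 11.61 ± 0.02 to 10.81 ± 0.10, a call lost after centring on the median of kept genes (difference -0.13). That list's camera adjusted p was 0.00476, and adjusted p = 0.345 with an estimated correlation.

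Receptors of chemokines, cytokines and growth factors rose in 23 of 26 tested genes and fell in 0, with the same counts adjusted over the list alone; 20 rose and 1 fell with arrays centred on the hybridization controls. The complement receptor gene C5ar1 rose from 8.46 ± 0.25 to 10.62 ± 0.08, Il17ra by 2.14, Ccr1 by 2.74 and Csf1r, the receptor of macrophage colony-stimulating factor, by 4.01. For the list, the camera adjusted p was 3.15e-09, and adjusted p = 0.294 with an estimated correlation. Among cytokines and chemokines 11 of 20 tested rose and 2 fell, also adjusted over the list alone, and 18 rose and 1 fell after centring on the median of kept genes. Cxcl2 rose from 2.28 ± 0.11 to 6.75 ± 0.70 (the former within the absent-transcript level, so that the size depends on background), Il15 by 2.54 and Osm by 3.56, while Vegfa fell from 6.17 ± 0.81 to 4.30 ± 0.50 and Tgfb1 from 4.20 ± 0.25 to 3.48 ± 0.10, the latter a call lost with that centring. That list's camera adjusted p was 6.91e-04, and adjusted p = 0.3 with an estimated correlation.

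Of 26 tested myeloid transcription factor genes 15 rose and 4 fell (16 and 4 adjusted over the list alone; 19 and 1 after centring on the median of kept genes; 15 and 7 with arrays centred on the hybridization controls). Junb rose from 3.05 ± 0.18 to 7.53 ± 0.45, Bcl6 by 1.78, Spi1, which encodes PU.1, by 1.13 and Cebpb by 1.27. Gfi1, a repressor needed for granulocyte development, fell from 11.20 ± 0.33 to 8.15 ± 0.42, and Id2 and Runx1 fell by 0.90 and 0.41, calls lost after the first centring, where they differed by -0.22 and 0.27. The camera adjusted p was 0.00357, and adjusted p = 0.294 with an estimated correlation, and it was 0.107 after centring on the median of kept genes (1.03e-04 to 0.294 over all alternatives).

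Immediate early and dissociation stress genes, which can respond to handling of cells, rose in 12 of 18 and fell in 3 (13 and 3 adjusted over the list alone; 14 and 1 after centring on the median of kept genes). Btg2 rose by 2.74, Ier3 by 2.70, Jund by 3.30, Socs3 by 5.82 and Fos from 8.92 ± 1.24 to 12.58 ± 0.11. The chaperone genes Hspe1 and Hspa8 fell by 2.49 and 0.70, the latter a call lost with that centring. This list's camera adjusted p was 4.07e-04, and adjusted p = 0.294 with an estimated correlation; it was 0.0597 after centring on the median of kept genes (3.40e-07 to 0.294 over all alternatives).

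In the histamine list 3 of 5 tested genes rose and 0 fell, with the same counts adjusted over the list alone. Among the 3 is Hdc, whose reporter was used to sort all cells and which was set as a check of the labels. After centring on the median of kept genes 5 rose, and 4 rose with repeated quantile normalization. Besides Hdc, the H2 receptor gene Hrh2 rose from 4.85 ± 0.28 to 6.66 ± 0.69 (adjusted p = 0.00111) and Hnmt, whose product inactivates histamine, rose from 8.86 ± 0.30 to 9.79 ± 0.27 (adjusted p = 0.00207). Slc18a2, the vesicular monoamine transporter gene, differed by 0.46 (adjusted p = 0.119, and 0.0371 without Gr1hi replicate 3), and Hrh1 by -0.06 (adjusted p = 0.728), whose sign turned after centring on the median of kept genes and without Gr1lo replicate 1. Aoc1, Slc18a1, Slc22a2, Hrh3, Hrh4 and Maob did not pass the filter on dim probe sets. The list did not pass the list test (camera adjusted p = 0.0663, and adjusted p = 0.322 with an estimated correlation), but did without Gr1hi replicate 1 (0.0492) and without Gr1hi replicate 3 (0.0468; 0.00114 to 0.322 over all alternatives).

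Of 24 tested monocyte genes 11 rose and 2 fell, with the same counts adjusted over the list alone, against 15 and 1 after centring on the median of kept genes and 10 and 5 with arrays centred on the hybridization controls. The lipopolysaccharide co-receptor gene Cd14, Treml4 (by 2.05), Clec4a3 (by 3.72) and Itgal (by 1.41) rose, and Spn and F13a1 fell by 1.68 and 0.98, the latter a call lost after the first centring. Of the members that did not pass, 3 chosen after their values were seen varied between replicates: Ccr2 stood at 4.75 ± 1.15 and 5.47 ± 1.62, Irf8 at 4.57 ± 0.69 and 3.88 ± 0.97 and Ly86 at 5.70 ± 0.93 and 5.65 ± 0.90. In replicate 3 of both groups Ccr2 exceeded the mean of replicates 1 and 2 by 1.98 and 2.73, Irf8 by 1.16 and 1.65 and Ly86 by 1.60 and 1.55. Without the replicate 3 arrays 9 monocyte genes rose and 5 fell. For the list, the camera adjusted p was 0.0109, and adjusted p = 0.437 with an estimated correlation; it was 0.0518 without Gr1hi replicate 3 and 0.204 after centring on the median of kept genes (5.29e-04 to 0.437 over all alternatives).

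Of 15 tested macrophage genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; 14 and 1 after centring on the median of kept genes; 7 and 2 with arrays centred on the hybridization controls). Cd68 rose from 4.93 ± 0.29 to 9.34 ± 0.35, Adgre1, which encodes F4/80, by 2.99 and Tgfbi by 2.62, while the adhesion molecule gene Vcam1 fell from 10.31 ± 0.28 to 5.05 ± 0.39. The macrophage genes Mertk, C1qa, C1qc, Cd163, Timd4, Axl, Marco and Fcna did not pass the filter on dim probe sets. The list's camera adjusted p was 0.00595, adjusted p = 0.323 with an estimated correlation, and 0.0707 after centring on the median of kept genes (7.20e-04 to 0.323 over all alternatives). In the dendritic cell and MHC class II list 7 of 15 rose and 0 fell, also adjusted over the list alone, and 3 rose with arrays centred on the hybridization controls, where the median was -0.05; Itgax rose by 3.29 (from 2.48 ± 0.38, within the absent-transcript level, so that the size depends on background), H2-Aa by 2.01 and Cd74 from 3.55 ± 0.39 to 4.98 ± 0.25. Ly6d, at 3.25 ± 0.21 and 3.82 ± 0.18, passed the test (adjusted p = 0.0114) but not without Gr1lo replicate 1 (0.0571). The dendritic cell genes Flt3, Zbtb46, Irf4, Xcr1, Cd209a and Clec10a did not pass the filter on dim probe sets. That list did not pass the list test (camera adjusted p = 0.0621), but did without Gr1hi replicate 1 (0.0386) and without Gr1hi replicate 2 (0.039; 0.0154 to 0.427 over all alternatives).

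Stem and progenitor genes fell in 7 of 13 tested and rose in 0, with the same counts adjusted over the list alone. The transcription factor gene Myb fell from 12.22 ± 0.07 to 10.31 ± 0.12, Prom1 by 1.34, Kit by 1.94 and Cd48 by 2.18. The camera adjusted p of 0.0422 became adjusted p = 0.294 with an estimated correlation, 0.0598 without Gr1lo replicate 3 and 0.072 without Gr1hi replicate 2, and after centring on the median of kept genes 4 rose and 4 fell (4.47e-04 to 0.294 over all alternatives).

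Markers of other marrow cells gave mixed directions. The counts below cover only members that passed the filter on dim probe sets. No list of this paragraph or the next 2 passed the camera test at an adjusted p under 0.05 in the main fit, with all arrays on the deposited scale. In the basophil and mast cell list 1 gene rose and 2 fell of 13 (list adjusted p = 0.634), while 9 rose and 2 fell after centring on the median of kept genes and 0 rose and 2 fell with arrays centred on the hybridization controls. Its mean was -0.12, its median 0.16 and its test pointed up. Ms4a2, a subunit of the IgE receptor, fell by 1.64 and Cyp11a1 rose by 0.38, a call lost without any 1 of 4 arrays (Gr1lo replicates 1 and 2, Gr1hi replicates 1 and 2; 0.0582 to 0.0684). Hgf stood at 4.60 ± 0.26 and 5.23 ± 0.53 (adjusted p = 0.0842, and 0.0362 without Gr1hi replicate 2), and the basophil protease gene Mcpt8 at 5.99 ± 1.27 and 5.33 ± 2.31. In the eosinophil list 1 of 3 rose, Il13ra1, from 3.90 ± 0.06 to 8.67 ± 0.13 (list adjusted p = 0.224). The eosinophil genes Epx, Prg3, Il5ra, Ccr3, Alox15 and Gata1 did not pass that filter. Prg2 read 3.94 ± 0.35 and 4.75 ± 1.09 (adjusted p = 0.166, and 0.00213 without Gr1hi replicate 2) and Siglecf 8.46 ± 0.34 and 8.17 ± 0.08 (0.214, and 0.0237 without Gr1lo replicate 3).

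In the B lineage list 7 of 15 rose and 1 fell (list adjusted p = 0.0663, 0.0453 with no filter and 0.0414 without Gr1hi replicate 1; 0.0113 to 0.656 over all alternatives), but 1 rose and 1 fell with arrays centred on the hybridization controls. Ms4a1 rose by 0.96, Ebf1 by 0.59, Dntt by 0.51 and Fcer2a by 0.47, each to under 4, and Cd79b fell by 0.74. In the T cell list 2 of 6 rose, 1 with arrays centred on the hybridization controls (list adjusted p = 0.117), Cd3d from 4.32 ± 0.69 to 8.49 ± 0.15 and Cd6 by 0.54; Cd4 at 3.30 ± 0.05 and 3.77 ± 0.41 (adjusted p = 0.073, and 0.0488 without Gr1hi replicate 1) and Lat at 2.65 ± 0.09 and 2.82 ± 0.08 did not pass. In the NK cell list 3 of 5 rose and 1 fell, but 0 rose and 1 fell with arrays centred on the hybridization controls (list adjusted p = 0.646), the fall being Nkg7 from 11.10 ± 0.49 to 4.79 ± 0.06. On the deposited scale Prf1 rose by 0.52, Eomes by 0.31 (lost without Gr1lo replicate 3, 0.0669, or Gr1hi replicate 2, 0.0585) and Klre1 by 0.25 (lost without any 1 of 5 arrays, all but Gr1hi replicate 2; 0.0554 to 0.131). The list's mean was -1.03 and its median 0.25, and its test pointed up, but down with arrays centred on the hybridization controls.

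In the erythroid list 2 of 10 fell (list adjusted p = 0.518), the transferrin receptor gene Tfrc from 10.85 ± 0.36 to 7.32 ± 0.41 and Hemgn by 1.96, while 7 rose and 2 fell after centring on the median of kept genes. Slc4a1 (3.37 ± 0.15 and 3.10 ± 0.14) and Sptb (2.82 ± 0.11 and 3.02 ± 0.17) did not pass. In the megakaryocyte and platelet list 3 of 7 rose and 1 fell, and 2 rose and 1 fell with arrays centred on the hybridization controls (list adjusted p = 0.224): Clec1b rose from 3.93 ± 0.38 to 6.93 ± 0.08, Itgb3 by 1.21 and Pf4 by 0.48, and Gp1bb fell by 0.96. With the mean of its probe sets Itgb3 differed by 0.57 and lost its call (limma adjusted p = 0.067). In the stromal and endothelial list 3 of 8 rose, Cdh5 by 0.49, Col1a1 by 0.45 and Pdgfrb by 0.36 (list adjusted p = 0.176), 2 adjusted over the list alone and 0 with arrays centred on the hybridization controls. The call of Pdgfrb was lost without any 1 of 5 arrays, all but Gr1hi replicate 1 (0.0501 to 0.0932), and Cxcl12 read 3.13 ± 0.07 and 3.28 ± 0.19. Pdgfrb differed by 0.12 with the mean of its probe sets (limma adjusted p = 0.235). For the other 7 lists of this and the previous 2 paragraphs the counts adjusted over the list alone were the same.

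In the NADPH oxidase list 3 of 6 rose, also adjusted over the list alone (Rac2 by 0.50, Rac1 by 0.41 and Ncf1 by 0.39), and 0 with arrays centred on the hybridization controls; Cyba read 13.30 ± 0.10 and 13.43 ± 0.08. The list adjusted p was 0.0624, and 0.046 without Gr1hi replicate 1 (0.0113 to 0.437 over all alternatives). In the lysosome list 12 of 30 rose and 7 fell (13 and 7 adjusted over the list alone; 23 and 2 after centring on the median of kept genes; 11 and 8 with arrays centred on the hybridization controls, where the median was -0.09), with the cathepsin genes Ctsl and Ctsd up by 2.33 and 2.12, Npc1 up by 2.09 and Glb1 down from 5.34 ± 0.23 to 3.25 ± 0.32. Its list adjusted p was 0.0701, and 0.0414 without Gr1hi replicate 1 (0.00535 to 0.427 over all alternatives).

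**Figure D3:**
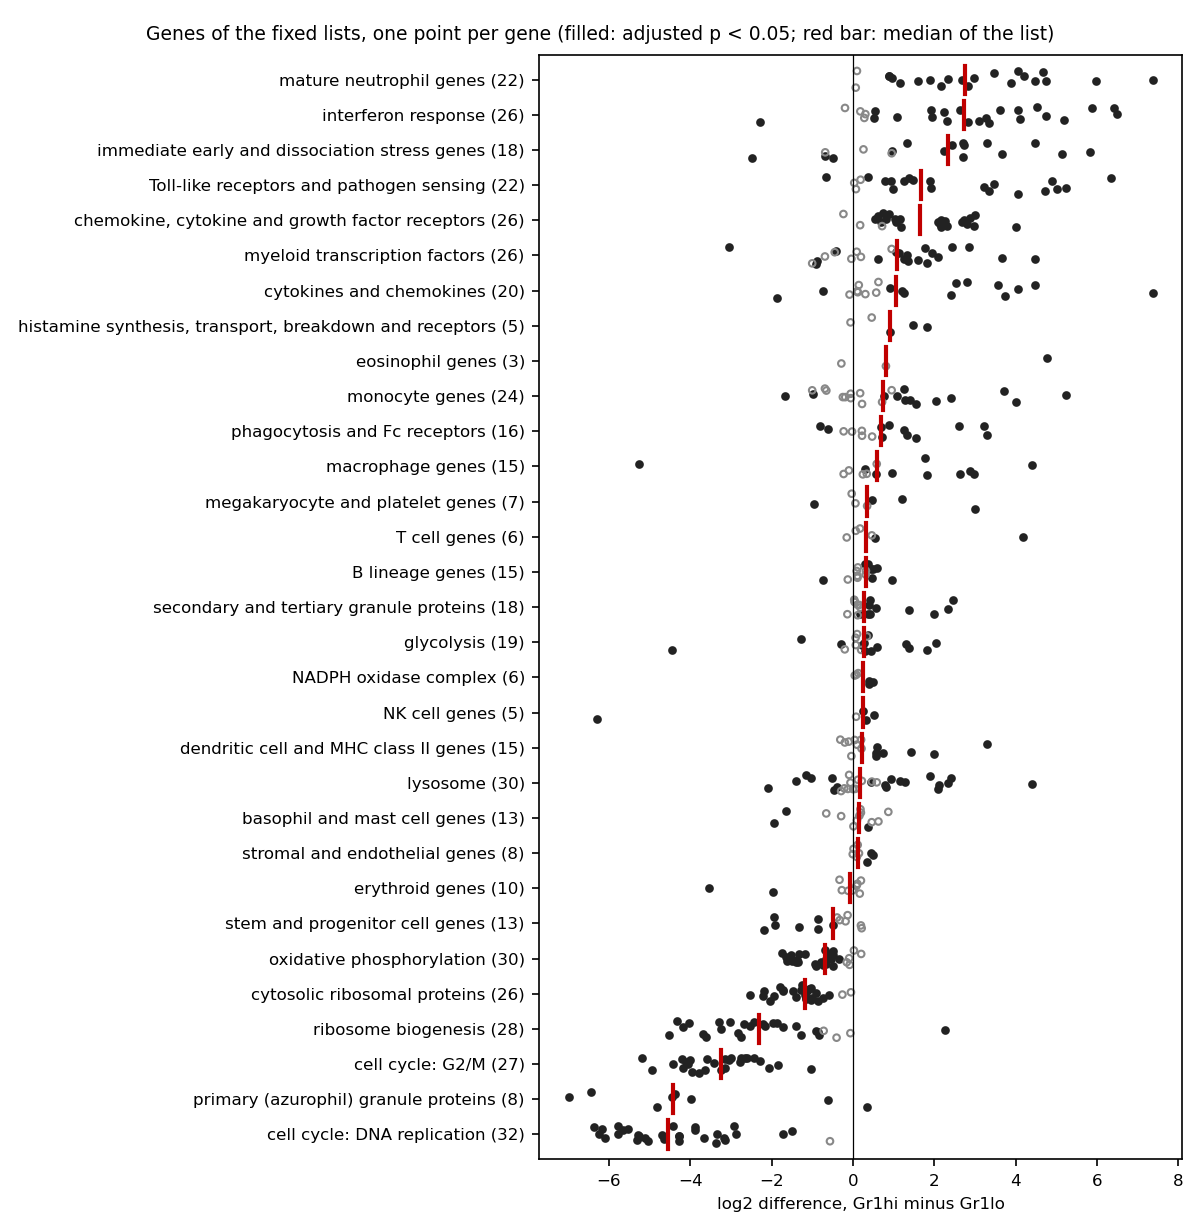
Log2 difference (Gr1hi minus Gr1lo) of each tested gene of the 31 lists fixed beforehand, with the number of tested genes in parentheses, filled points for genes with an adjusted p under 0.05, open points for the others and a red bar at each list's median. The DNA replication, G2/M and primary granule lists lie lowest and the mature neutrophil and interferon lists highest; arrays centred on the median of kept genes move every point up and turn the oxidative phosphorylation list from 25 falls and 0 rises to 12 falls and 6 rises.

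In all, 18 of the 31 lists passed the camera test with a preset correlation between genes, and 0 did with the correlation estimated from the data, where 4 had an unadjusted p under 0.05 and fry, a rotation test of each list on its own, called 30. After centring on the median of kept genes, which raises every difference, 18 of 18 secondary and tertiary granule genes, 17 of 19 glycolysis genes (2 fell), 14 of 15 dendritic cell genes, 13 of 15 B lineage genes, 8 of 8 stromal genes, 6 of 7 megakaryocyte genes, 6 of 6 T cell genes, 6 of 6 NADPH oxidase genes and 4 of 5 NK cell genes (1 fell) rose. The falls of Cd79b and Gp1bb lost their call with that centring, under which Ltf, Lcn2, Camp, Ngp, S100a8 and S100a9 rose. With arrays centred on the hybridization controls the rises of Srgn, Ly6d, Cyp11a1, Ebf1, Dntt, Fcer2a, Cd6, Prf1, Eomes, Klre1, Pf4, Cdh5, Col1a1, Pdgfrb, Rac1, Rac2 and Ncf1 lost their call. The arrays of the groups separated fully on the 3' minus 5' signal of Actb (0.85 ± 0.09 in Gr1lo and 0.72 ± 0.06 in Gr1hi) and on the hybridization controls (8.02 ± 0.16 and 8.28 ± 0.06), each with an exact permutation p = 0.1, the smallest that 3 against 3 arrays allow. The exact permutation p was 0.3 for the 3' minus 5' signal of Gapdh, 0.2 for the absent-transcript controls and 0.5 for the poly-A controls.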

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

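The tests of cells of female mice alone, of a mixture of sexes, of monocytes and basophils, and of T and NK cells were chosen after the results were seen, as were the settings without both replicate 3 arrays.

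Xist was not among the tested genes, yet it read 10.95 in Gr1lo replicate 3 and 10.14 in Gr1hi replicate 3, and no higher than 2.43 on the other arrays. Whether the replicate 3 arrays differed as a whole cannot be told from the genes that moved by over 4 log2 units. Arrays within a group correlated at 0.992 or above, so many such genes were unlikely from the start. In both groups 1 gene, Xist itself, moved that far the same way. That bound cannot exclude a smaller shared difference of these arrays, and 18 genes moved by over 1 log2 unit the same way. Cells of female mice alone in replicate 3 are argued against, because Eif2s3y there lay at least 6.544 log2 units above the absent-transcript controls. A mixture of cells of male and female mice in replicate 3 may account for both signals, as Eif2s3y and Kdm5d were lower in replicate 3 than in replicates 1 and 2, by a mean of -0.7919. The same arrays held more Ccr2, Ly86 and Mcpt8 transcript, and whether a larger share of monocytes and basophils entered those sorts cannot be told apart from other sources: the monocyte list shifted by a median of 0.498 in Gr1lo and 0.596 in Gr1hi, past the bound of 0.2 set for it, with 11 of its 21 members above background over 0.5 in both groups against 0.874% of all such genes, but the basophil and mast cell list by 0.147 and 0.0754, short of that bound, and the macrophage list by 0.249 in Gr1hi, over the limit set for it. Of the 17 basophil and mast cell genes 3 moved by over 0.5 in both groups. Among them Mcpt8 moved by 2.17 and 3.61 and Cpa3 by 1.23 and 1.79. Other members, such as Cma1, Cd200r3 and Mcpt4, did not pass the filter on dim probe sets, so the list's median can miss a shift of a few members. Whether mice of both sexes were pooled stays open, since the labels give a single sex.

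Cd3d, a chain of the T cell receptor complex, was higher in Gr1hi by 4.17, and Nkg7, a gene of cytotoxic granules, differed by -6.31. T cells in the Gr1hi sort are argued against, because the other 14 measured T cell genes had a median difference of 0.1006 (SD 0.22) and the highest of them, Cd8a, a level of 3.70. NK cells in the Gr1lo sort are argued against too, because the other 14 measured NK cell genes had a median difference of 0.2142 (SD 0.174), higher in Gr1hi, and the highest of them, Klra8, a level of 3.30. Both lists were fixed before the data were examined, and the CD11b gate selects against T cells. Expression of Cd3d and Nkg7 by the sorted myeloid cells, and signal of another transcript, stay open and were not tested.

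Genes near the background level tended to be higher in Gr1hi: of 3372 tested genes below 3.37 in both groups 566 were called, 67.8% of them higher, and their median difference was 0.10. A shift of the background between the groups' arrays may add to these calls, since 33 of 43 measured genes of tissues outside blood were higher in Gr1hi, with a median of 0.05006. It cannot be told apart from true low expression, because 67.8% lies between the bounds of 60% and 80% set beforehand. The SD of the 43 differences was 0.295, but they include Mbp, which lay far above background (8.73 in Gr1lo and 10.32 in Gr1hi). Among the dim ones Prm1 differed by 0.62, Gad1 by 0.59 and Ryr1 by -0.58. The rises of Ebf1, Dntt, Fcer2a, Cd6, Prf1, Eomes, Klre1, Pf4, Cdh5 and Col1a1 were no larger than that of Prm1. Their size thus cannot tell them from background signal. Of the 6613 called genes above 3.37 in a group, 41.5% were higher in Gr1hi. Low expression that truly differs between the Gr1lo and Gr1hi cells stays open and was not tested.

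The poly-A spike-in controls, which the comparisons do not use, were higher in replicate 1 than in replicates 2 and 3, by 0.9147 in Gr1lo and 0.6682 in Gr1hi. Of 5123 kept probe sets that name no single gene, 2354 were called, 1481 higher and 873 lower in Gr1hi.

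The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 7179 genes and the highest of the others 0, so 1 split gave as many. The counts were 3817 against 0 for genes at least 2-fold different, 3128 against 0 for genes higher in Gr1hi and 4051 against 0 for genes lower in Gr1hi, with 1 split as large in each case. The camera test with its preset correlation called 18 lists for the real split and up to 19 for the others, and 4 of the 10 splits called at least 18. Each other split mixes Gr1lo and Gr1hi arrays on both sides. It thus keeps part of the group difference and adds the rest to the spread within sides. These counts of genes and lists therefore cannot show what arrays without a group difference would give.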

How the results depend on the processing

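Settings with both replicate 3 arrays left out, a replicate 3 factor, a filter at log2 5 and centring on hybridization controls were chosen after seeing the data. Hdc and Itgam kept direction and call in each setting that was run for single genes (not each probe set on its own, the threshold of 0.01 or the 1.5-fold test), and 107 of 139 named genes did in those where they were tested; stricter filters left some untested. Of 31 lists 0 kept both in each setting run for them. That count was fixed by the settings that swap the list test. An estimated correlation weakened the 18 called lists, and fry strengthened 11 and reversed 2 of the others. Where all 31 lists were tested, each other setting left at least 25 unchanged, the fewest without Gr1hi replicate 1. The labels do not say that a replicate number marks a shared animal or day. Arrays with the same number deviated together in replicates 1 and 3 (correlations of deviations 0.166 and 0.145, and Xist in replicate 3 of both groups) but not in replicate 2 (0.00429). Deviations sum to 0 within a group, so the replicate 2 value is not independent of the others. The poly-A controls were also higher in replicate 1 of both groups. Not every array correlated best with its own number. The numbers were not taken as pairs in the main fit, but a source shared by number cannot be excluded. With the replicate block 7059 genes were called (3038 higher, 4021 lower); of the named genes it added calls of Kdm5d (adjusted p = 0.0174), Prg2 (0.0442) and Hgf (0.0446) and did not call Klre1 and Pdgfrb. The number of genes called ranged from 6446 to 6792 with 1 array left out and was 6214 without both replicate 3 arrays. Testing each probe set on its own gave 15123 calls (7450 higher, 7673 lower, 7689 at least 2-fold), because more features are tested. Centring on the median of kept genes gave 8354 higher and 2313 lower, and centring on the hybridization controls 1861 higher, because each adds a constant to every difference. Of 31 lists, camera with an estimated correlation called 0 (4 at an unadjusted p under 0.05) and fry 30.

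Reversed directions of list tests and of genes named by the rule were the following, and unless a shift of scale is named the cause was not tested. For the basophil and mast cell list (mean -0.12) and the NK cell list (mean -1.03) fry pointed down where camera pointed up; the means did not turn. Camera itself pointed down for the former with the log2 5 filter (mean -1.13) and for the latter with hybridization centring (mean -1.29). Median centring turned Hrh1 to 0.62, Siglecf to 0.39 and Slc4a1 to 0.40. Hybridization centring turned Lat to -0.082, Klre1 to -0.0088, Sptb to -0.060, Cxcl12 to -0.11, Cyba to -0.13 and Uty to -0.23. The mean of probe sets turned Slc4a1 to 0.016 and Uty to -0.26, and Uty was -0.072 without both replicate 3 arrays. With an array left out Hrh1 ran from -0.18 to 0.042 and Uty from -0.13 to 0.17. Outside these, among others, median centring turned Ly86 to 0.62, Mcpt8 to 0.019, Runx1 to 0.27, Pycard to 0.024, the erythroid mean to 0.11, the basophil mean to 0.56 and the stem median to 0.19, and hybridization centring turned the glycolysis mean to -0.084, the stromal mean to -0.049, Ltf to -0.099, Lcn2 to -0.15, Camp to -0.22, Ngp to -0.14, S100a8 to -0.19 and S100a9 to -0.16. Signal over background limits the dim genes: 3372 tested genes lay below 3.37 in both groups.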

Other observations

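The gene families in this part, the patterns of symbols that define them and the comparison of replicates were all chosen after the data were seen.

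In further families, of protein synthesis, folding and breakdown and of nuclear transport, more genes fell than rose in Gr1hi. Of 76 tested mitochondrial ribosomal protein genes 67 fell and 2 rose (54 and 8 after centring on the median of kept genes), with Mrpl35 falling from 9.05 ± 0.32 to 5.41 ± 0.07 (SD, n = 3 per group). The camera adjusted p was 6.15e-13, and adjusted p = 0.293 with an estimated correlation. Of 19 aminoacyl-tRNA synthetase genes 18 fell and 0 rose (11 and 0 after that centring), Iars from 8.95 ± 0.58 to 4.09 ± 0.57 (camera adjusted p = 2.28e-06, and adjusted p = 0.293 with an estimated correlation). All 8 tested subunit genes of the CCT chaperonin fell under each scaling, Tcp1 by 2.65 (camera adjusted p = 1.26e-04, and adjusted p = 0.293 with an estimated correlation). Of 18 nucleoporin genes 17 fell and 0 rose (16 and 1 after that centring), Nup205 from 9.99 ± 0.17 to 5.55 ± 0.27 (camera adjusted p = 3.11e-07, and adjusted p = 0.293 with an estimated correlation). Of 38 proteasome subunit genes 31 fell and 0 rose, but 13 fell and 7 rose after that centring, with Psmc3 falling by 1.39 (camera adjusted p = 1.34e-06, and adjusted p = 0.296 with an estimated correlation).

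Of 21 mitochondrial import genes 17 fell and 2 rose (13 and 5 after centring on the median of kept genes), Timm50 by 3.53 (camera adjusted p = 4.74e-04, and adjusted p = 0.296 with an estimated correlation). Of 9 snRNP genes 8 fell and 0 rose (7 and 1 after that centring), Snrpe by 2.06 (camera adjusted p = 3.73e-04, and adjusted p = 0.293 with an estimated correlation). Of 10 RNA polymerase II subunit genes 8 fell and 0 rose, but 4 and 2 after that centring, Polr2i by 1.55 (camera adjusted p = 0.00411, and adjusted p = 0.295 with an estimated correlation). Of 10 replication origin and GINS genes 9 fell and 0 rose (8 and 1 after that centring), Gins1 by 5.53 (camera adjusted p = 1.98e-04, and adjusted p = 0.293 with an estimated correlation).

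In other families more genes rose than fell in Gr1hi. All 6 tested IFITM genes rose, 4 with arrays centred on the hybridization controls, among them Ifitm1 from 8.87 ± 1.12 to 13.42 ± 0.32 (camera adjusted p = 0.00267, and adjusted p = 0.293 with an estimated correlation). Of 7 Schlafen genes 6 rose and 1 fell (5 and 1 with that centring), Slfn1 from 5.41 ± 0.76 to 10.03 ± 0.12 (camera adjusted p = 0.00698, and adjusted p = 0.293 with an estimated correlation). Of 27 autophagy genes 13 rose and 4 fell (11 and 4 with that centring), Map1lc3b from 11.05 ± 0.20 to 12.67 ± 0.22 (camera adjusted p = 0.00609, and adjusted p = 0.293 with an estimated correlation). Of 51 Rab GTPase genes 24 rose and 4 fell, but 13 and 5 with that centring, where their median was 0.01 (camera adjusted p = 0.00155, and adjusted p = 0.293 with an estimated correlation). Of 16 C-type lectin genes 8 rose and 3 fell (7 and 3 with that centring), Clec4e by 3.46 (camera adjusted p = 0.00858, and adjusted p = 0.293 with an estimated correlation). Of 16 V-ATPase subunit genes 9 rose and 2 fell, but 3 and 2 with that centring (camera adjusted p = 0.0347, and adjusted p = 0.296 with an estimated correlation). After centring on the median of kept genes 23 autophagy, 47 Rab, 14 lectin and 15 V-ATPase genes rose and 1, 0, 0 and 0 fell.

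The camera test was not passed by the guanylate-binding proteins (2 of 3 rose and 0 fell, 1 fell with arrays centred on the hybridization controls; adjusted p = 0.12), the TRIM family (18 of 42 rose and 9 fell, but 33 and 7 after centring on the median of kept genes and 10 and 11 with arrays centred on the hybridization controls; 0.0621) or the dual-specificity phosphatases (6 of 17 rose and 3 fell, but 14 and 0, and 4 and 4, with these centrings; 0.109). Nor was it passed by the cathepsins (7 of 12 rose and 3 fell, and 9 and 1, and 5 and 3, with these centrings; 0.0621), annexins (3 of 8 rose and 0 fell, but 8 and 0, and 2 and 0; 0.0621), S100 proteins (2 of 9 rose and 1 fell, but 7 and 1, and 1 and 1; 0.311) or kinesins (6 of 29 rose and 13 fell, but 17 and 10, and 3 and 13; 0.126).

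The Gr1lo replicates differed from each other partly along the direction of the group difference. Across genes, Gr1lo replicate 1 minus replicate 2 correlated with the Gr1hi mean minus Gr1lo replicate 3 (r 0.529). Gr1lo replicate 3 minus replicate 2 correlated with the Gr1hi mean minus Gr1lo replicate 1 (r 0.572). Gr1lo replicate 1 minus replicate 3 did not follow the Gr1hi mean minus Gr1lo replicate 2 (r -0.162). Both positive correlations subtract Gr1lo replicate 2, so they may rest on that 1 array. Differences between 2 Gr1hi arrays, set against the remaining Gr1hi array minus the Gr1lo mean, gave correlations from -0.0984 to -0.0164. Genes are not independent, so no p-value is given.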
